A study of Mus musculus with 2 samples.

How the data were processed

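H3K27ac was measured by chromatin immunoprecipitation and sequencing in embryonic day 16.5 mouse kidneys, in 2 biological replicates from libraries of 300 to 500 bp, per the labels. All samples formed 1 group, so no comparison between conditions was possible. Input or control libraries were not analysed here.

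The authors deposited 4 peak lists in narrowPeak format on the mm10 build. Per the records deposited with the samples, peaks were called on each replicate alone and on both together, and the replicated list was derived from these 3 lists. The aligner, the peak caller, its thresholds and the overlap rule of the replicated list were not given in the sources used here. Each peak carries the authors' signal value, whose scaling was not given in the sources used here, so signals were used to describe, rank or filter peaks within a list and to correlate pairs. Each peak also carries -log10 p and -log10 q values as deposited by the authors; -log10 q started at 0.359 in replicate 1, 0.468 in replicate 2 and 0.446 in the other lists, so the lists hold weak peaks. Peaks with -log10 q of at least 5 made up 35.0% of the replicate 1 list, 44.6% of replicate 2, 47.3% of the pooled and 68.2% of the replicated list. Median peak lengths were 291, 341, 362 and 518 bp in the same order. The lists give no read counts, so differences in library depth could shift the number and length of peaks and could not be corrected for.

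Peaks on the chromosomes entered the analysis, and 9 or 10 peaks per list on unplaced scaffolds were left out. Coordinates are 1-based on mm10, which is the GRCm38 assembly of the reference sequence used here. Genes were the 21938 protein-coding genes of GENCODE release M21, with 54361 TSSs. Peaks of the replicates were compared by overlap, counted as shared where the overlap covered at least 50% of either peak, with Wilson 95% intervals for counting error. Chance was taken from 100 circular shifts of the peaks along each chromosome. Spearman's rho and Pearson's r of log2 signal were computed over the best overlapping pairs. A gene counted as marked when a peak lay within 1 kb of any of its TSSs. Marked shares of 23 gene lists were tested against all other protein-coding genes with a two-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 23 lists with a threshold of 0.05. The lists held 295 genes besides the olfactory receptors, and all were found in the annotation. Their names were nephron progenitor, early nephron, podocyte, proximal tubule, loop of Henle and distal tubule, ureteric bud and collecting duct, renal stroma, endothelium, macrophage and leukocyte, erythroid, peripheral neuron and Schwann cell, adrenal cortex, germ cell, liver, muscle, forebrain neuron, pluripotency, 3 sets of Hox genes, housekeeping, cell cycle and olfactory receptor. A peak near a TSS can belong to a neighbouring gene, and a list of 14 genes can show only large differences. Cover was the number of bp within 50 kb of a gene's most 5' TSS under a peak, and the median over a list's marked members was placed among 10000 random lists of marked genes where at least 3 members were marked. Domains were peaks at most 10 kb apart joined together and ranked by the sum of signal times length, and the top 20 are described.

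Motif matches on both strands were counted in the central 400 bp of replicated peaks with no TSS within 1 kb and in 400 bp windows 5 kb to each side outside any peak. The ratio of matches per window was placed among up to 200 permutations of the motif's letters, which keep base composition but not CpG pairs. A motif was described as standing out at or above the 95th percentile of these.

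The named genes followed a rule. They were, for each of the top 20 domains, the coding gene inside with the highest promoter signal, or the nearest TSS where none lay inside. They were also, for each list, the 4 marked members with the most cover and up to 3 members in alphabetical order with no promoter peak in either replicate, any Hox gene, and for each replicate the 5 genes with the highest promoter signal there and no peak within 1 kb of a TSS in the other. Not every gene that meets the rule is named, and genes named outside it are said to be so. The groups, lists, motifs, tests, alternatives and this rule were fixed before the data were examined, apart from the choices named in the closing section. The alternatives tried were overlaps of 1 bp or of 50% of both peaks, peaks with -log10 q of at least 5, equal numbers of top peaks, autosomes, -log10 p in place of signal, promoter windows of 500 bp and 2 kb, all annotated transcripts, 1 TSS per gene, the pooled list, windows of 20 and 100 kb, joining distances of 5 and 20 kb, ranking by covered bp, motif windows of 200 bp, flanks 2 kb away, and each replicate's list in place of the replicated list.

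The calculations were tested on simulated data. Of simulated lists of 14 genes, 91.0% of those marked at 95% and 89.5% of those marked at 10% were called, and 1.92% of lists marked at the 54% of other genes. Simulated genes were marked independently of each other and of CpG content, so these rates do not cover lists whose genes share peaks or differ in CpG content. A planted share of 59.9% of overlapping peaks was recovered exactly, a planted correlation of 0.8 was recovered as 0.800, and a motif planted at a ratio of 7.24 was recovered at 7.03. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and samtools 1.23.1 were used.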

Results

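H3K27ac, an acetylated form of histone H3 found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the kidneys of mouse embryos at embryonic day 16.5, a stage at which new nephrons are still being formed. The samples formed 1 group of 2 biological replicates of the strain B6NCrl, each a pool of kidneys from male and female embryos. Replicate 2 pooled the kidneys of 41 embryos, and the number behind replicate 1 was not given in the sources used here. The replicate 1 list held 93470 peaks covering 43.4 Mb, and the replicate 2 list held 114998 peaks covering 64.4 Mb. A pooled list held 103976 peaks over 61.6 Mb, and a list of replicated peaks held 70176 peaks over 53.5 Mb. Peak lists carry no read counts, so the depth of each library is unknown. With no second group, the comparisons were between the marked genome and chance, between gene lists and other genes, and between the replicates.

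The Hox clusters, whose transcription factors set position along the body axis, held 4 of the 8 highest ranked H3K27ac domains of the replicated list. Domains were replicated peaks at most 10 kb apart joined together, and all 25752 were ranked by the sum over their peaks of the authors' signal times length. The HoxB cluster ranked 1 in the replicated list and in both replicates, on chromosome 11 from 96250213 to 96356513. Its 18 peaks covered 100.3 kb of 106 kb, and its score was 1.75 times that of rank 2. A peak of 56018 bp, from 96291503 to 96347520, ran over the whole bodies of Hoxb6, Hoxb5 and Hoxb4. The HoxA cluster ranked 3 (chromosome 6, 52158408 to 52249905, 78.8 kb covered), the HoxD cluster ranked 4 (chromosome 2, 74675059 to 74753485, 61.2 kb covered) and the HoxC cluster ranked 8 (chromosome 15, 102954469 to 103041339, 60.2 kb covered). HoxA ranked 3 in both replicates. HoxD ranked 4 in replicate 1 and 6 in replicate 2, and HoxC ranked 10 in replicate 1 and 8 in replicate 2. The genes with the highest promoter signal in these domains were Hoxb8 (ENSMUSG00000056648.5) and Hoxb7, which shared a peak, the annotated coding gene Gm28308 (ENSMUSG00000101298.1) and Hoxa3, which shared another, Hoxd8 (ENSMUSG00000027102.4) and Hoxc9 (ENSMUSG00000036139.6).

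At the ends of the clusters the mark did not reach every Hox gene. All 10 genes of Hox groups 9 to 11, which include the Hox11 genes needed for kidney formation, had a promoter peak, and a median of 92.5% of their bodies was covered (82.7 to 100%; medians of 87.3% in replicate 1 and 93.0% in replicate 2). Of the 6 genes of groups 12 and 13, Hoxd12 (ENSMUSG00000001823.5, chromosome 2, 74675013 to 74677705) was marked and 96.0% covered, with 82.2% in replicate 1 and 99.1% in replicate 2. Hoxa13 (ENSMUSG00000038203.18, chromosome 6, 52257694 to 52260880), Hoxb13 (ENSMUSG00000049604.3, chromosome 11, 96194316 to 96197447), Hoxc12 (ENSMUSG00000050328.2, chromosome 15, 102936757 to 102938609), Hoxc13 (ENSMUSG00000001655.6, chromosome 15, 102921103 to 102928814) and Hoxd13 (ENSMUSG00000001819.4, chromosome 2, 74668310 to 74671599) had no promoter peak and 0% of their bodies covered in the replicated list and in both replicates. At the other flank, 21 of 23 genes of groups 1 to 8 were marked. The unmarked pair was Hoxb1 (ENSMUSG00000018973.2, chromosome 11, 96365752 to 96368256) and Hoxd1 (ENSMUSG00000042448.5, chromosome 2, 74762980 to 74765142), at 0% body cover in both replicates. Hoxa1 (ENSMUSG00000029844.9, chromosome 6, 52155590 to 52158317) had a peak within 1 kb upstream of its TSS and 0% of its body covered. Fisher's exact test called groups 1 to 8 (adjusted p = 9.46e-04) and groups 9 to 11 (adjusted p = 0.00570) marked more often than other genes. The test counts Hox genes as independent, but neighbours in a cluster share promoter peaks, so these p values are too small. The 1 of 6 in groups 12 and 13 did not pass (exact adjusted p = 0.115).

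**Figure D1:**
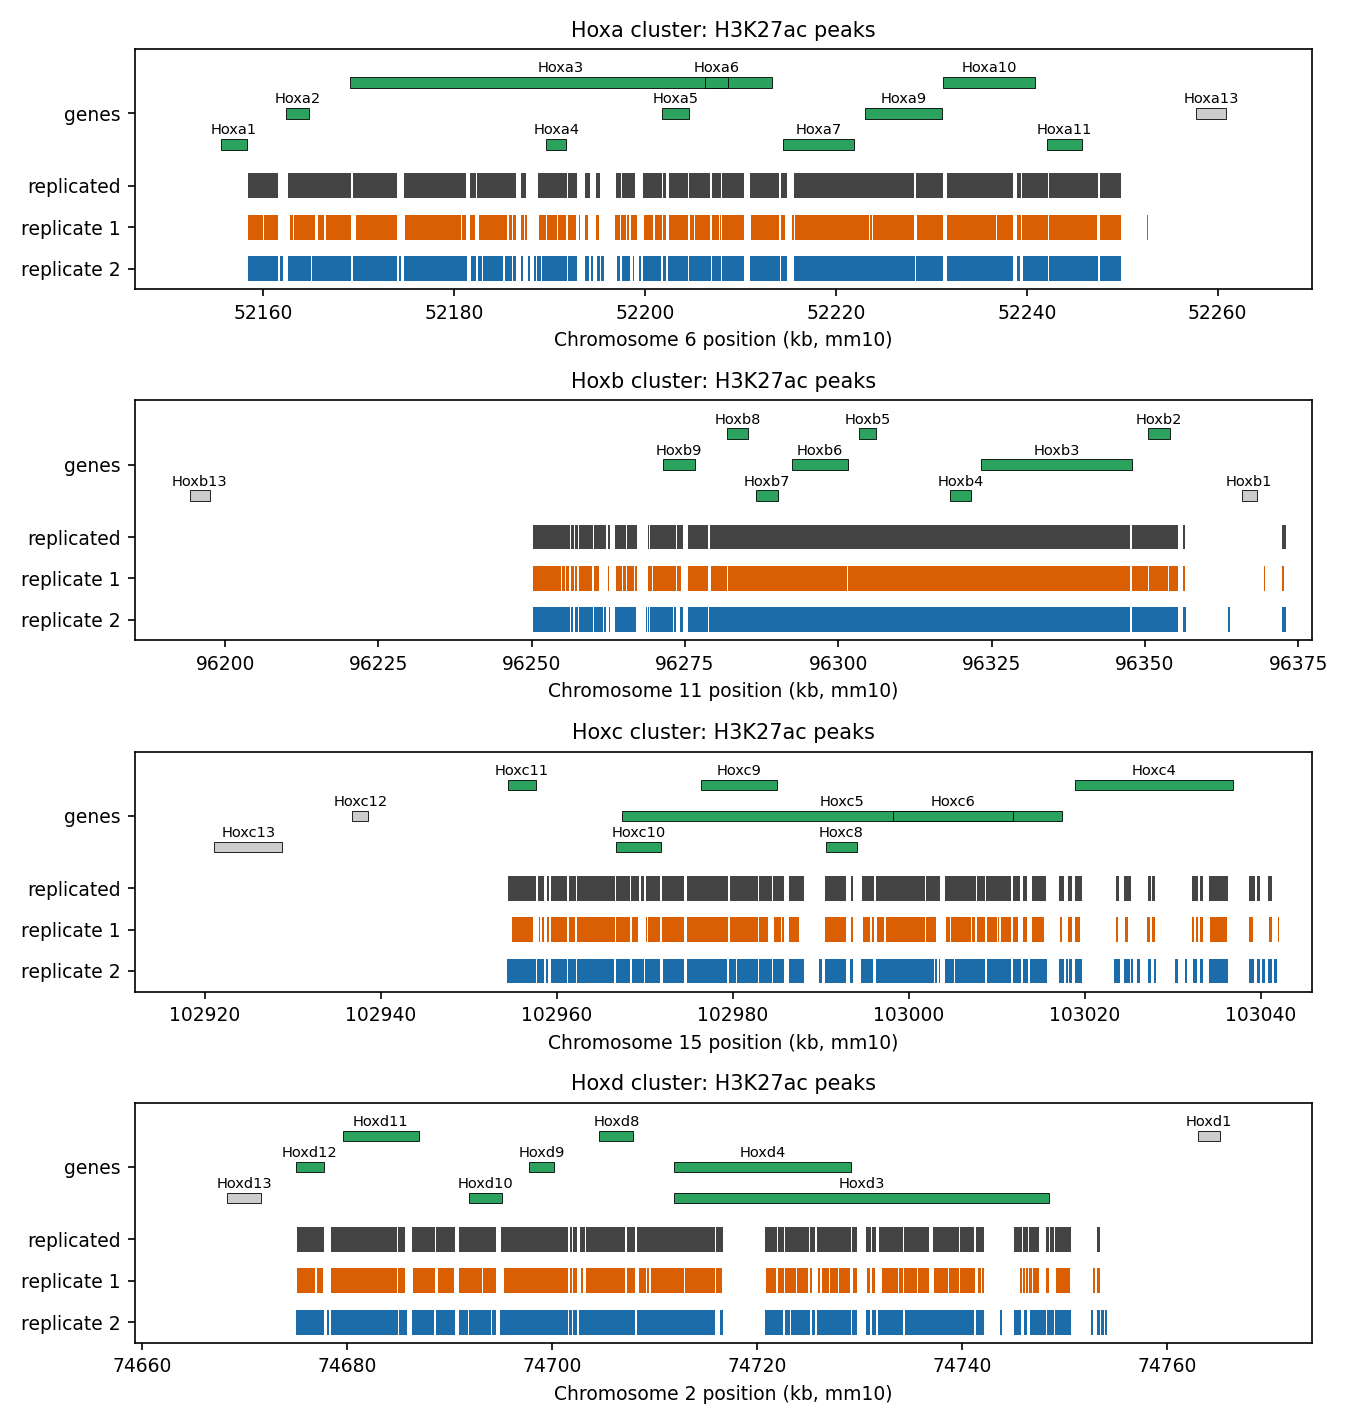
H3K27ac peaks over the 4 Hox clusters, with position in kb (mm10) on each horizontal axis. Bars are peaks of the replicated list and of each replicate, and gene bodies are green where a replicated peak lay within 1 kb of a TSS and grey where none did; Hoxa13, Hoxb13, Hoxc12, Hoxc13, Hoxd13, Hoxb1 and Hoxd1 are grey.

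Outside the Hox clusters, some of the top 20 domains held a single coding TSS, and others held several or none. Rank 2, on chromosome 2 from 30636632 to 30796908 with 49 peaks, held no protein-coding TSS; the nearest, of 1700001O22Rik (ENSMUSG00000044320.14), was 4799 bp away, and the domain ranked 2 in both replicates. Ranks 5 to 7 held Trim8 (ENSMUSG00000025034.9, chromosome 19, 46440489 to 46535154), Zmynd8 (ENSMUSG00000039671.18, chromosome 2, 165820110 to 165923122) and Cxxc5 (ENSMUSG00000046668.9, chromosome 18, 35813263 to 35895822). Rank 9 held Nr2f2 (ENSMUSG00000030551.14, chromosome 7, 70330727 to 70371893), an orphan nuclear receptor of mesenchyme and venous endothelium. Rank 12 held Smad7 (ENSMUSG00000025880.11, chromosome 18, 75366211 to 75406137), an inhibitor of TGF-beta signalling, and rank 20 held Id3 (ENSMUSG00000007872.3, chromosome 4, 136103985 to 136149641), an inhibitor of basic helix-loop-helix factors. Others were Ahdc1 in a domain with 2 coding TSSs (rank 10), Irf2bpl (rank 11), Bahcc1 (rank 13) and Tnrc18 (rank 17). Midn lay in a domain with 6 coding TSSs (rank 14), and the histone gene Hist1h3e in one with 14 (rank 16). Rank 15 (chromosome 19, 5787426 to 5850324) contained the long non-coding RNA genes Malat1 and Neat1 (like H19 below, named after their position was seen), with the nearest coding TSS, of Scyl1 (ENSMUSG00000024941.9), 16007 bp away. Rank 18 (chromosome 4, 144923854 to 145083194) lay 30717 bp from the TSS of Dhrs3 (ENSMUSG00000066026.14), a retinaldehyde reductase. Rank 19 (chromosome 7, 142499234 to 142579189) contained Mrpl23 (ENSMUSG00000037772.13), Tnnt3 and the imprinted gene H19. Of these 20 domains, 18 were among the top 20 of replicate 1 and 15 among those of replicate 2; the lowest ranks were 40 in replicate 1 (Tnrc18) and 26 in replicate 2 (the Hist1h3e domain). Ranked by covered bp alone, 12 of the 20 stayed in the top 20.

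Genes of 5 of the 8 kidney cell types listed were marked at their promoters more often than other genes. A replicated peak lay within 1 kb of a TSS in 13 of 14 nephron progenitor genes, 12 of 14 early nephron genes, 14 of 16 ureteric bud and collecting duct genes, 17 of 18 renal stroma genes and 14 of 14 endothelial genes, against 11889 of all 21938 protein-coding genes (54.2%). The two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 23 lists gave adjusted p = 0.00570 for nephron progenitors, 0.0358 for early nephrons, 0.0149 for ureteric bud and collecting duct, 0.00172 for stroma and 9.46e-04 for endothelium. The tests compare genes within this peak set and carry no spread between embryos, and each of these 5 lists also passed in replicate 1 alone and in replicate 2 alone.

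Among nephron progenitor genes, which maintain the cap mesenchyme, Pax2 (ENSMUSG00000004231.15, chromosome 19, 44756045 to 44837871) had the most cover, 28088 bp within 50 kb of its TSS (26356 bp in replicate 1 and 29398 bp in replicate 2). Its promoter peak of 3611 bp had a signal of 22.9. Wt1 (ENSMUSG00000016458.14, chromosome 2, 105126529 to 105173616) had 17352 bp, the zinc finger gene Sall1 (ENSMUSG00000031665.7, chromosome 8, 89027235 to 89044162) had 16122 bp with a promoter peak of 7118 bp, and the homeobox gene Meox1 (ENSMUSG00000001493.9, chromosome 11, 101877510 to 101894374) had 10174 bp. Six1 (ENSMUSG00000051367.8, chromosome 12, 73040015 to 73053887) had no promoter peak in either replicate. With -log10 q of at least 5, 64.3% of the list was marked and the call was lost (exact adjusted p = 0.445).

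Among early nephron genes, Pax8 (ENSMUSG00000026976.15, chromosome 2, 24420560 to 24475599) had 24748 bp of cover, the Notch ligand gene Jag1 (ENSMUSG00000027276.7, chromosome 2, 137081456 to 137116644) had 20356 bp, Hnf1b (ENSMUSG00000020679.11, chromosome 11, 83850063 to 83905819) had 19646 bp and Pou3f3 (ENSMUSG00000045515.3, chromosome 1, 42695768 to 42703176) had 18378 bp. The growth factor gene Fgf8 (ENSMUSG00000025219.13, chromosome 19, 45736798 to 45742915) had no promoter peak in either replicate. This call was also lost with -log10 q of at least 5, at 78.6% (exact adjusted p = 0.0835).

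In the ureteric bud and collecting duct list, Gata3 (ENSMUSG00000015619.10, chromosome 2, 9857078 to 9890034) had 23207 bp of cover, the keratin gene Krt8 (ENSMUSG00000049382.10, chromosome 15, 101996698 to 102004482) had 18247 bp, Wnt7b (ENSMUSG00000022382.15, chromosome 15, 85535437 to 85582473) had 12984 bp and the water channel gene Aqp3 (ENSMUSG00000028435.8, chromosome 4, 41092722 to 41098183) had 10733 bp. The 2 unmarked members, named after their values were seen, were the receptor gene Ret (ENSMUSG00000030110.13, chromosome 6, 118151745 to 118197718), with a promoter peak in replicate 1 alone, and Wnt9b (ENSMUSG00000018486.2, chromosome 11, 103727364 to 103749821), with one in replicate 2 alone. The call was lost with -log10 q of at least 5, at 68.8% (exact adjusted p = 0.256), and with 1 TSS per gene, at 75% (adjusted p = 0.0950).

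Stromal genes included the strongest single promoter peak among the named kidney genes, that of Pbx1 (ENSMUSG00000052534.15, chromosome 1, 168119364 to 168432270), a homeobox gene, with a signal of 40.1 (32.2 in replicate 1 and 40.7 in replicate 2) and 28347 bp of cover. Meis2 (ENSMUSG00000027210.20, chromosome 2, 115863064 to 116065839) had 28050 bp, the collagen gene Col1a1 (ENSMUSG00000001506.10, chromosome 11, 94936224 to 94953042) had 20725 bp and Meis1 (ENSMUSG00000020160.18, chromosome 11, 18879817 to 19018985) had 17346 bp. The renin gene Ren1 (ENSMUSG00000070645.5, chromosome 1, 133350510 to 133360325) was the stromal member with no promoter peak in either replicate, though 5002 bp within 50 kb were covered. In the endothelial list, the TGF-beta co-receptor gene Eng (ENSMUSG00000026814.16, chromosome 2, 32646595 to 32682669) had 21334 bp, Plvap (ENSMUSG00000034845.6, chromosome 8, 71497765 to 71511752) 19478 bp, Ets1 (ENSMUSG00000032035.15, chromosome 9, 32636221 to 32757820) 16687 bp and the adhesion gene Pecam1 (ENSMUSG00000020717.19, chromosome 11, 106654217 to 106750628) 12480 bp. Plvap had no promoter peak in the replicate 1 list, where 13 of the 14 endothelial genes were marked.

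**Figure D2:**
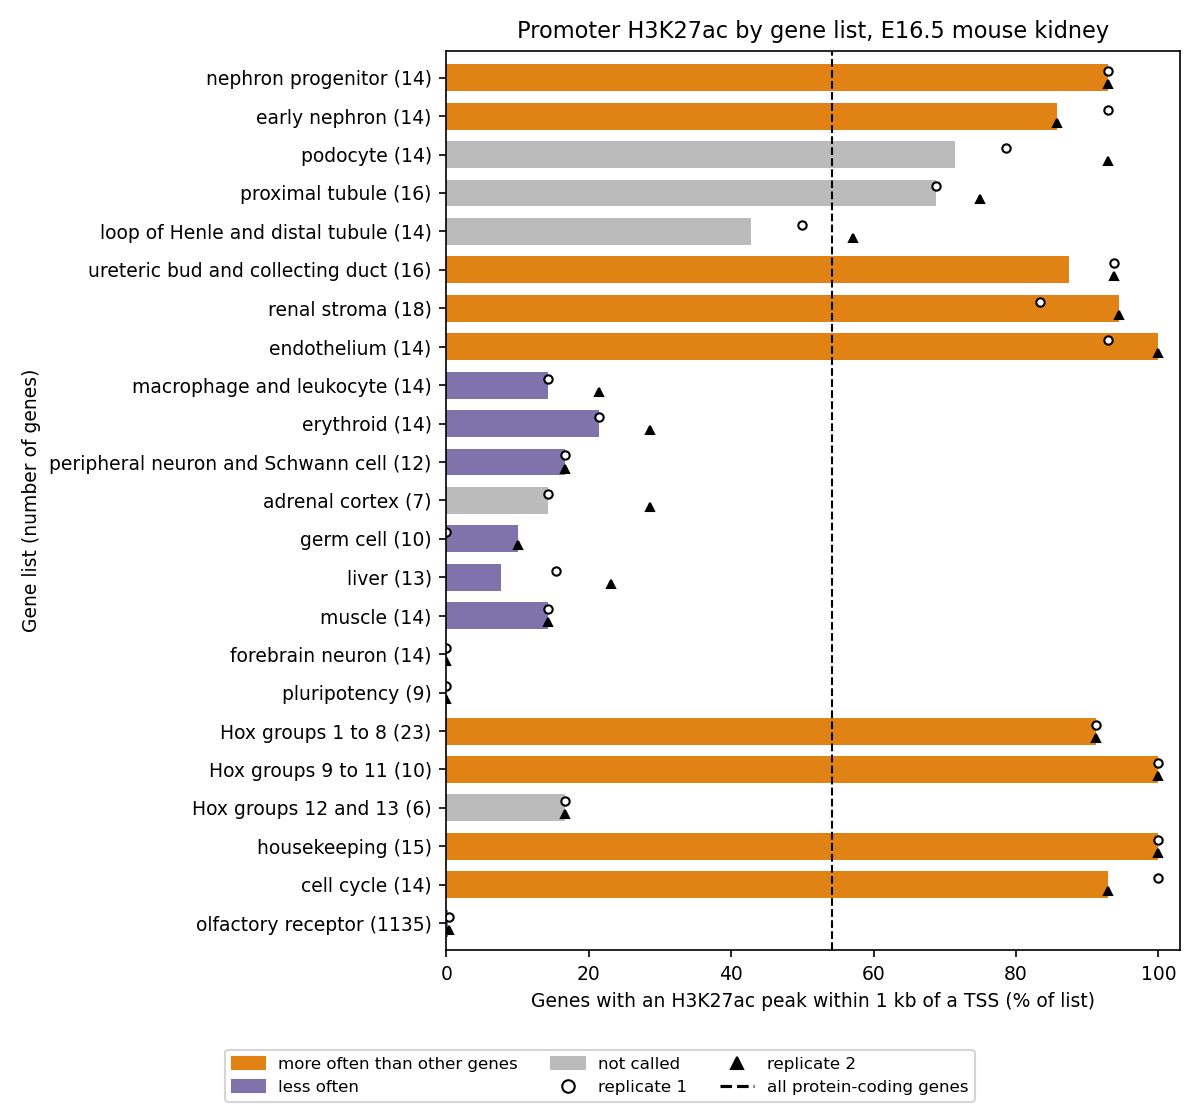
Share of each gene list with an H3K27ac peak within 1 kb of a TSS, in per cent, with the number of genes in parentheses. Bars give the replicated list, coloured by the Fisher's exact test call against other genes, circles and triangles give replicates 1 and 2, and the dashed line is the 54.2% of all protein-coding genes; the endothelial list reaches 100% and the forebrain list 0%.

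Segments of the maturing nephron were marked at levels that did not differ detectably from other genes. Podocyte genes were marked in 10 of 14 (adjusted p = 0.311), proximal tubule genes in 11 of 16 (adjusted p = 0.332) and loop of Henle and distal tubule genes in 6 of 14 (adjusted p = 0.431) by Fisher's exact test. Marked podocyte genes included the adhesion gene Kirrel (ENSMUSG00000041734.15, chromosome 3, 87078593 to 87174747) with 17957 bp of cover, Foxc2 (ENSMUSG00000046714.7, chromosome 8, 121116171 to 121118895) with 13681 bp, Tcf21 (ENSMUSG00000045680.8, chromosome 10, 22817281 to 22820174) with 13607 bp, and Foxc1 (ENSMUSG00000050295.4, chromosome 13, 31806633 to 31812476) with 12174 bp and a promoter signal of 31.2. The 4 unmarked podocyte genes, named after their values were seen, were Nphs1 (nephrin; ENSMUSG00000006649.17, chromosome 7, 30458315 to 30487223), Nphs2 (podocin; ENSMUSG00000026602.9, chromosome 1, 156310727 to 156328035), Ptpro (ENSMUSG00000030223.14, chromosome 6, 137252319 to 137463233) and Lmx1b (ENSMUSG00000038765.13, chromosome 2, 33560965 to 33640511). Each had a promoter peak in at least 1 replicate list but none in the replicated list. The podocyte call therefore depended on the list: 11 were marked in replicate 1 (exact adjusted p = 0.115), 13 in replicate 2 (adjusted p = 0.0102) and 12 in the pooled list (adjusted p = 0.0384).

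In the proximal tubule list, Ggt1 (ENSMUSG00000006345.10, chromosome 10, 75561604 to 75586200) had 18432 bp of cover, Hnf1a (ENSMUSG00000029556.12, chromosome 5, 114948980 to 114971094) had 13409 bp with a promoter signal of 18.9, Pdzk1 (ENSMUSG00000038298.14, chromosome 3, 96829284 to 96870926) had 9875 bp and the urate transporter gene Slc22a12 (ENSMUSG00000061742.12, chromosome 19, 6535845 to 6543032) had 8026 bp. The fructose bisphosphatase gene Fbp1 (ENSMUSG00000069805.10, chromosome 13, 62864753 to 62888282), Slc27a2 (ENSMUSG00000027359.16, chromosome 2, 126552407 to 126588243) and Slc5a12 (ENSMUSG00000041644.14, chromosome 2, 110597298 to 110647779) had no promoter peak in either replicate. In the loop and distal tubule list, Sim1 (ENSMUSG00000019913.4, chromosome 10, 50894754 to 50989152) had 6284 bp of cover and a promoter signal of 10.6, and Tfap2b (ENSMUSG00000025927.13, chromosome 1, 19208914 to 19238576) had 5466 bp and 5.48. The chloride channel gene Clcnkb (ENSMUSG00000006216.10, chromosome 4, 141404353 to 141416014) had 5430 bp and 3.93, and Umod (ENSMUSG00000030963.6, chromosome 7, 119462711 to 119479282), which encodes uromodulin, had 2935 bp and 3.71. Cldn16 (ENSMUSG00000038148.13, chromosome 16, 26463135 to 26482765), Esrrb (ENSMUSG00000021255.17, chromosome 12, 86361117 to 86521628) and Ptger3 (ENSMUSG00000040016.16, chromosome 3, 157566892 to 157645888) had none in either replicate.

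Genes of other tissues were marked less often than other genes. No forebrain neuron gene of 14 (adjusted p = 2.05e-04, Fisher's exact test) and no pluripotency gene of 9 (adjusted p = 0.00283) had a promoter peak, in the replicated list or in either replicate. Among them Foxg1 (ENSMUSG00000020950.10, chromosome 12, 49382660 to 49386861), Dlx1 (ENSMUSG00000041911.3, chromosome 2, 71528113 to 71533981) and Dlx2 (ENSMUSG00000023391.8, chromosome 2, 71543408 to 71546754) had 0 bp covered within 50 kb. Liver genes were marked in 1 of 13 (exact adjusted p = 0.00283), the transferrin gene Trf (ENSMUSG00000032554.15, chromosome 9, 103204001 to 103230444), while the albumin gene Alb (ENSMUSG00000029368.10, chromosome 5, 90460897 to 90476602) and Afp (ENSMUSG00000054932.6, chromosome 5, 90490737 to 90508907) had no promoter peak. In the replicate 1 list 2 liver genes were marked (exact adjusted p = 0.00767), and in the replicate 2 list 3 were (adjusted p = 0.0284). Muscle genes were marked in 2 of 14 (exact adjusted p = 0.00885), Tnnt3 (ENSMUSG00000061723.18, chromosome 7, 142498836 to 142516009) and Actn3 (ENSMUSG00000006457.4, chromosome 19, 4861216 to 4877909), and germ cell genes in 1 of 10 (adjusted p = 0.0121), Dazl (ENSMUSG00000010592.9, chromosome 17, 50279395 to 50293636), whose peak was absent from the replicate 1 list. Of 1135 olfactory receptor genes, 3 were marked (0.264%): Olfr986, Olfr214 and Olfr1342.

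Cell types that the kidney also contains in small numbers were marked less often as well. Macrophage and leukocyte genes were marked in 2 of 14 (adjusted p = 0.00885, Fisher's exact test): Cd68 (ENSMUSG00000018774.13, chromosome 11, 69664213 to 69666153) and Aif1 (ENSMUSG00000024397.14, chromosome 17, 35170991 to 35176068). The complement genes C1qa (ENSMUSG00000036887.5, chromosome 4, 136895917 to 136898803) and C1qb (ENSMUSG00000036905.8, chromosome 4, 136880129 to 136886187) had no promoter peak in either replicate. Erythroid genes were marked in 3 of 14 (exact adjusted p = 0.0221): Nfe2 (ENSMUSG00000058794.12, chromosome 15, 103248212 to 103258403), Tal1 (ENSMUSG00000028717.12, chromosome 4, 115056426 to 115071755) and Epor (ENSMUSG00000006235.6, chromosome 9, 21958897 to 21963506). Peripheral neuron and Schwann cell genes were marked in 2 of 12 (exact adjusted p = 0.0221): Erbb3 (ENSMUSG00000018166.8, chromosome 10, 128567523 to 128589652), with a signal of 14.5, and the myelin gene Mpz (ENSMUSG00000056569.10, chromosome 1, 171150711 to 171161130), with 9.03. Adrenal cortex genes, from the neighbouring gland, were marked in 1 of 7, the cholesterol transporter gene Star (ENSMUSG00000031574.8, chromosome 8, 25806555 to 25815982), which did not pass (exact adjusted p = 0.0641). The erythroid call was lost with a 2 kb promoter window (exact adjusted p = 0.0705) and in replicate 2 alone (adjusted p = 0.0657), and the peripheral neuron call with a 2 kb window (adjusted p = 0.0574). Without its 4 globin genes the erythroid list had 30% of 10 genes marked, and this call was lost too (exact adjusted p = 0.234).

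Housekeeping and cell cycle genes were marked more often than other genes. All 15 housekeeping genes had a promoter peak (adjusted p = 8.42e-04, Fisher's exact test), led in signal by the actin gene Actb (ENSMUSG00000029580.14, chromosome 5, 142903115 to 142906754) at 47.7, with 34.6 in replicate 1 and 50.2 in replicate 2. Gapdh (ENSMUSG00000057666.18, chromosome 6, 125161715 to 125166467) had a signal of 14.9. Of 14 cell cycle genes, 13 were marked (exact adjusted p = 0.00570), among them Aurkb (ENSMUSG00000020897.12, chromosome 11, 69045647 to 69051664), Rrm2 (ENSMUSG00000020649.11, chromosome 12, 24708241 to 24714146), Top2a (ENSMUSG00000020914.17, chromosome 11, 98992943 to 99024189) and Pcna (ENSMUSG00000027342.14, chromosome 2, 132249162 to 132253314).

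Marked Hox genes stood in the broadest surroundings of H3K27ac, and other lists above chance depended on the window or the replicate. Median cover within 50 kb was 66731 bp in groups 1 to 8 and 53259.5 bp in groups 9 to 11, against 4707 bp over all marked genes. Both lay at the 100 percentile of 10000 random lists of marked genes, there and under every alternative. Hox genes of a cluster have overlapping windows, unlike most genes of random lists, so their cover values are not independent. Marked early nephron genes had 11938.5 bp (percentile 99.92), but fell to percentile 89.39 in the replicate 1 list. Podocyte genes (10601 bp, percentile 98.91) fell to 88.33 in the replicate 1 list and 86.18 with a 100 kb window. Ureteric bud and collecting duct genes (7943 bp, percentile 95.62) fell below the 95th percentile in both replicates (93.83 in replicate 2 and 91.16 in replicate 1), in the pooled list (90.93) and with windows of 20 kb (85.68) and 100 kb (71.95). Stromal genes (7731 bp, percentile 95.68) and housekeeping genes (11010 bp, percentile 99.78) fell below it with 100 kb alone (59.07 and 91.39). The 3 marked erythroid genes (15600 bp, percentile 98.04) did so with 20 kb (81.49), with 100 kb (90.31) and in replicate 2 (91.94). Nephron progenitor genes had 3445 bp (percentile 18.27), although Pax2, Wt1 and Sall1 had 16122 bp or more. Endothelial (7018 bp, percentile 89.73; 95.15 with 20 kb), proximal tubule (5642 bp, percentile 67.88), cell cycle (5236 bp, percentile 62.79), loop and distal tubule (4182.5 bp, percentile 37.71) and olfactory receptor genes (496 bp over 3 marked genes, percentile 0.23) lay below the 95th percentile. The percentiles describe this peak set, and peaks of neighbouring genes count towards the cover. With a 100 kb window, 3 lists in place of 8 reached the 95th percentile, and in the replicate 1 list 5 did.

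Replicated peaks were concentrated at promoters. Of the 70166 on the chromosomes, 17380 (24.8%; 22.7% in replicate 1 and 18.5% in replicate 2) lay within 1 kb of a protein-coding TSS, against a median of 3.46% (2.98 to 3.94%) over 100 circular shifts of the peaks along their chromosomes. Gene bodies outside promoters held 31181 peaks (44.4%, shifts 38.3%), of which 29368 had a centre outside exons, and 21605 lay between genes (30.8%, shifts 58.2%). Promoter peaks had a median length of 751 bp and a median signal of 6.67. Peaks in gene bodies had 470 bp and 3.85, and peaks between genes had 471 bp and 3.98. The promoter share was 31.3% among peaks with -log10 q of at least 5 and 31.6% when all annotated transcripts were used.

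Away from promoters, the peak-to-flank ratios of the TEAD, forkhead, HNF1 and HOX motifs reached the 95th percentile of their letter permutations. The central 400 bp of 52786 promoter-distal peaks were set against 84002 windows of the same size 5 kb away and outside any peak. The TEAD consensus GGAATG, bound by partners of the YAP coactivator, occurred at 1.24 times its flank rate, above 98.3% of 59 permutations of its letters (median 1.01). The forkhead consensus TGTTTAC had a ratio of 1.13, above 99.0% of 200 permutations (median 0.890). The HNF1 core GTTAAT had 0.936 against a permutation median of 0.730, and the HOX consensus TTTATGG had 0.997 against 0.8005, so that neither exceeded its flank rate, but they lay above 98.3% and 98.1% of permutations. GC content was 48.6% in peak windows and 44.7% in flanks. Permutations do not keep CpG pairs. The TEAD, HNF1 and HOX motifs hold no C, so none of their permutations holds a CpG. Permutations of the E-box, ETS and CTCF motifs can, and their median ratios were 1.31, 1.36 and 1.59. Percentiles are therefore not comparable between motifs. The remaining motifs did not reach the 95th percentile: AP-1 at 1.17 (percentile 93.0), the SIX2 consensus at 1.66 (percentile 92.5), the E-box at 1.58 (percentile 88.1), HNF4 at 1.32 (percentile 88.0), ETS at 1.67 (percentile 87.5), GATA at 0.831 (percentile 82.8), the paired nuclear receptor site at 0.530 (percentile 51.7, 4 matches in peaks) and the CTCF core at 0.746 (percentile 5.18). The 4 motifs kept their position with flanks 2 kb away, with stricter peaks and in each replicate, and 3 did in windows of 200 bp, where HOX fell below it (ratio 0.949).

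**Figure D3:**
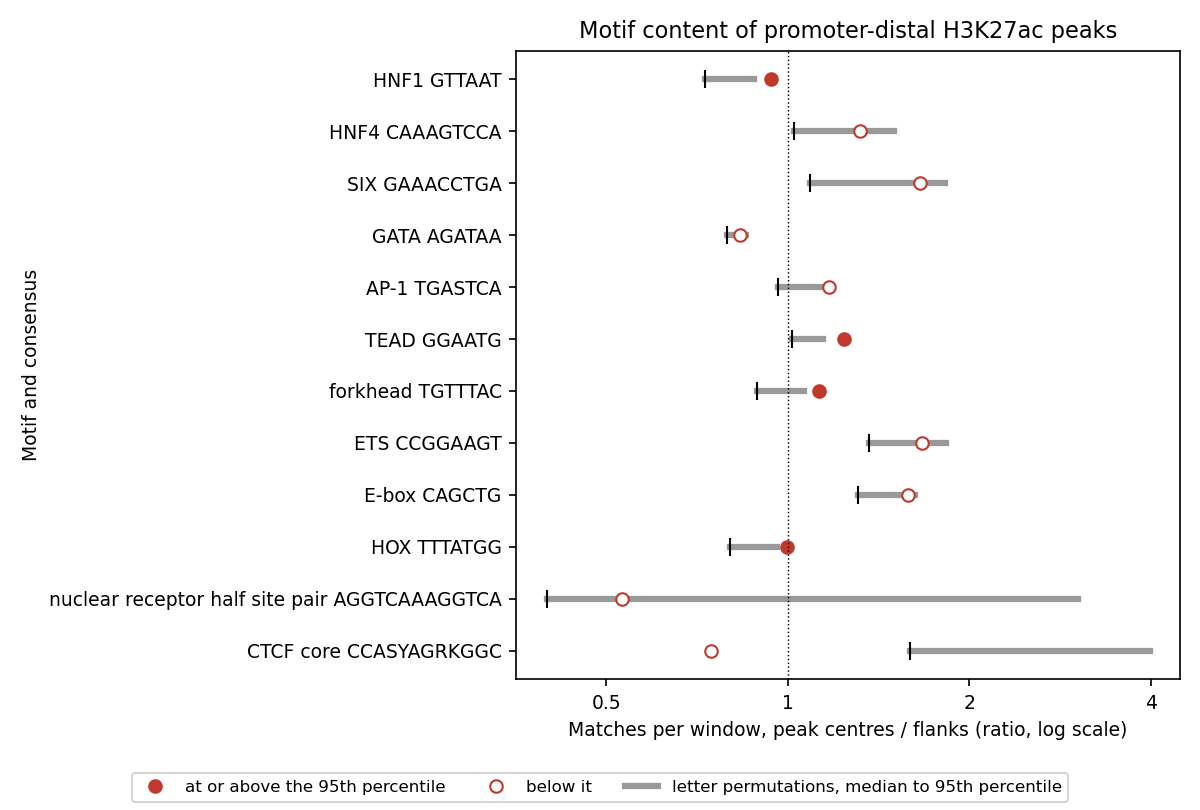
Ratio of motif matches per window in the central 400 bp of promoter-distal peaks to flanks 5 kb away, on a log scale, for 12 motifs fixed in advance. Circles are the motifs, filled at or above the 95th percentile of letter permutations, and grey bars run from the permutations' median to their 95th percentile; TEAD (1.24), forkhead (1.13), HNF1 (0.936) and HOX (0.997) are filled.

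The replicates shared nearly all of their peaks of highest signal, and most unshared peaks were weak. A peak counted as shared where an overlap covered at least 50% of either peak. Of replicate 1's peaks, 75.3% (Wilson 95% interval 75.0 to 75.6%) were shared, against a median of 3.26% when replicate 2's peaks were shifted along the chromosomes 100 times. Of replicate 2's larger set, 50.5% (50.3 to 50.8%) were shared, against 2.54% after shifts. Of peaks with -log10 q of at least 5, 97.8% in replicate 1 and 82.0% in replicate 2 were shared with a peak of any strength in the other, and 92.4% and 52.0% with a peak that also had -log10 q of at least 5. Of the genes with a promoter peak in either replicate, 11718 had one in both, 298 in replicate 1 alone and 852 in replicate 2 alone. Across 70387 overlapping pairs the log2 signal correlated with Spearman's rho 0.620 and Pearson's r 0.715; peaks are not independent replicates, so no p was computed. With an overlap of at least 50% of both peaks, 42.0% of replicate 1's and 34.1% of replicate 2's peaks were shared. The intervals cover counting error only.

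The authors' replicated list was a subset of the pooled list, with all 70176 peaks at the coordinates of a pooled peak and 67.5% of pooled peaks kept. It kept all of the 59415 pooled peaks that both replicates overlapped. It also held 9188 peaks overlapped in replicate 2 alone and 1480 in replicate 1 alone, and 83 overlapped in neither. By 1 bp, 9098 replicated peaks (12.97%) had no overlap in replicate 1 and 1411 (2.01%) had none in replicate 2. The peaks overlapped in both replicates had a median signal of 4.54, against 3.26 for those in replicate 2 alone and 3.12 for those in replicate 1 alone.

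Peaks seen in a single replicate were short, weak and mostly away from promoters. Replicate 1 had 23074 unshared peaks with a median signal of 3.09 and a median length of 201 bp, against 3.99 and 359 bp for its shared peaks. Replicate 2 had 56862, with 3.23 and 245 bp against 5.09 and 585 bp. The promoter share was 9.87% of replicate 1's unshared and 26.9% of its shared peaks, and 8.85% against 28.0% in replicate 2. Of the unshared peaks, 3.06% in replicate 1 and 16.3% (9242) in replicate 2 had -log10 q of at least 5.

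Among genes marked in replicate 1 alone, the highest promoter signals were those of Rbfa (ENSMUSG00000024570.7, chromosome 18, 80192265 to 80200658) at 6.73, Kcnh8 (ENSMUSG00000035580.10, chromosome 17, 52602709 to 52979194) at 6.15, Nebl (ENSMUSG00000053702.16, chromosome 2, 17343909 to 17731464) at 5.10, and 4930522L14Rik (ENSMUSG00000072762.9, chromosome 5, 109735990 to 109751886) and Alg11 (ENSMUSG00000063362.13, chromosome 8, 22060721 to 22071627) at 4.98 each. Among genes marked in replicate 2 alone they were those of Sspo (ENSMUSG00000029797.13, chromosome 6, 48448229 to 48501250) at 19.03, Vpreb1 (ENSMUSG00000059305.12, chromosome 16, 16868403 to 16870843) at 17.8, Nxnl1 (ENSMUSG00000034829.8, chromosome 8, 71560555 to 71566601) at 15.1, 1810010D01Rik (ENSMUSG00000109305.1, chromosome 7, 145205825 to 145208119) at 14.2 and the zinc finger gene Zfp445 (ENSMUSG00000047036.8, chromosome 9, 122844529 to 122866006) at 10.2. The peaks at Sspo, Vpreb1, Nxnl1 and 1810010D01Rik overlapped a replicate 1 peak that ended 1058 to 1179 bp from the TSS, just outside the window. The Kcnh8 peak overlapped a replicate 2 peak that ended 1003 bp from its TSS. At Zfp445 the nearest replicate 1 peak was 20820 bp away. Over all 852 genes marked in replicate 2 alone, 18 peaks (2.11%) were shared with replicate 1 and 75.8% had -log10 q under 5; over the 298 in replicate 1 alone these were 1 peak (0.336%) and 96.98%.

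**Figure D4:**
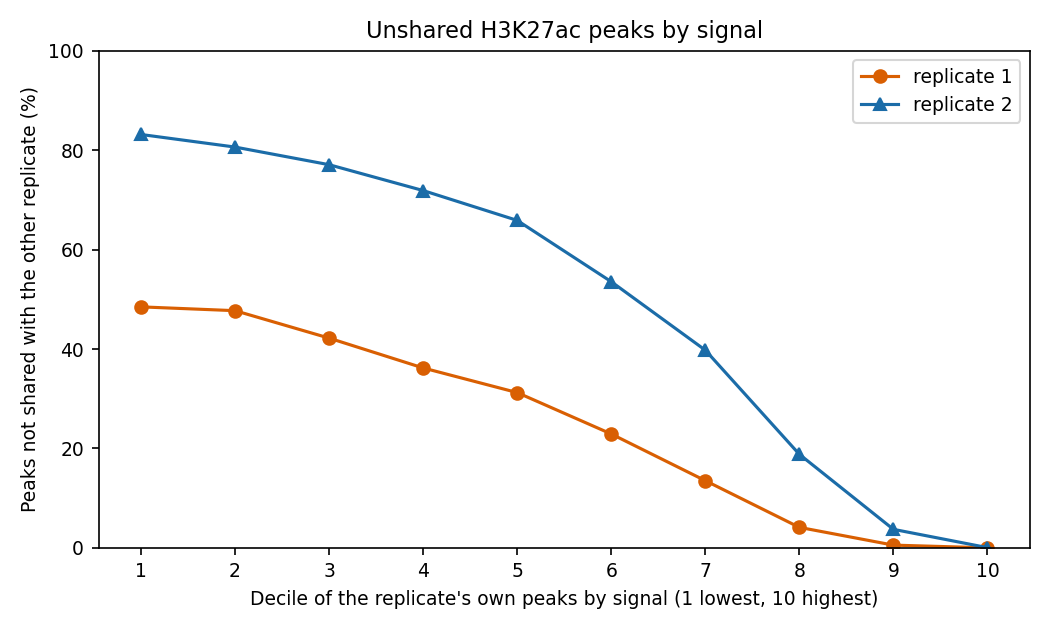
Per cent of each replicate's peaks not shared with the other, by decile of that replicate's own peaks in signal (1 lowest, 10 highest). Circles are replicate 1 and triangles replicate 2; the share falls from 48.5% to 0% in replicate 1 and from 83.2% to 0.0435% in replicate 2.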

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

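The tests of weak peaks, of partial overlaps, of CpG content and gene copies list by list, and the count of peaks outside the chromosomes were chosen only after the result was seen. The test of the mix of cell types was written before. Tests of CpG content and gene copies over all called lists together were also written before, but the lists differed in outcome and each was then weighed by itself.

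A signal appeared in data that the comparisons did not use: 10 replicated peaks lay on 5 unplaced or unlocalised scaffolds, above the limit of 3 that a count of 0 allows. No expectation of 0 was tested, and the count is a description. They covered 5469 bp, with signals from 2.04 to 40.9, and the strongest, of 1892 bp on an unlocalised scaffold of chromosome 4, had 33.4 in replicate 1 and 40.2 in replicate 2.

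Replicate 2 held more unshared peaks than replicate 1, 56862 against 23074. With the same number of top peaks by signal taken from each list (93461), the counts were 39190 against 26821. Part of the difference thus went with the longer list of replicate 2, which still held more. Partial overlaps counted as unshared are argued against as the main source, since 7.86% of replicate 2's unshared peaks touched a replicate 1 peak by 1 bp or more, and with an overlap of 1 bp the counts were still 52391 against 18642. Weak peaks near the calling threshold stay open. Of the peaks with -log10 q of at least 5, 18.0% of replicate 2's (9242) were unshared with a peak of any strength. In replicate 1 it was 2.15% (705), with Wilson 95% intervals of 17.7 to 18.4% and 2.00 to 2.32%. But over overlapping pairs the median ratio of replicate 1's to replicate 2's -log10 p was 0.628. A replicate 2 peak could enter several pairs, so this ratio also depends on how peaks were split. The same cut may therefore not be equally strict in the 2 lists, and the test cannot decide. A different mix of cell types in the 2 pools stays open: 0 lists passed the threshold for more genes marked in replicate 2 alone than other genes, yet fewer than 5 such genes were expected in every kidney list, and the podocyte list came closest (3 of 14, adjusted p = 0.177, Fisher's exact test). Depth was not given and stays open too, and no biological explanation was tested, since the design has 1 group.

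Of the 9 lists marked more often than other genes, CpG content of the promoters was weighed list by list, because marked shares ranged from 5.88% in the lowest decile of genes by CpG content to 91.3% in the highest. It is argued against as the whole source for these lists above the central 95% of CpG-matched lists: stroma (94.4% against 33.3 to 66.7%), endothelium (100% against 28.6 to 71.4%) and housekeeping (100% against 53.3 to 86.7%). The match used the most 5' TSS, whereas marking counted any TSS. With 1 TSS per gene these lists still lay above those ranges (94.4%, 85.7% and 93.3% in the same order), which were not recomputed for that setting. The ureteric bud list (87.5% against 37.5 to 75%) fell to 75% with 1 TSS per gene, the upper edge of its range. That range was not recomputed with 1 TSS per gene, so the match cannot decide for the ureteric bud list, and CpG content stays open there. It is a candidate explanation for the early nephron list (85.7%, inside 57.1 to 92.9%). It stays open for nephron progenitors, at the edge of their range (92.9%, range to 92.9%), and for Hox 9 to 11 (100%) and cell cycle genes (92.9%), whose ranges reach 100%. No biological explanation of the list calls was tested.

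Of the 9 lists marked less often, CpG content is argued against for those below their matched ranges: peripheral neuron (16.7% against 33.3 to 75%), germ cell (10% against 30 to 80%), forebrain (0% against 35.7 to 78.6%), pluripotency (0% against 22.2 to 77.8%) and olfactory receptors (0.264% against 10.2 to 13.6%). It is a candidate explanation for the erythroid list (21.4%, inside 7.14 to 50%). It stays open for the liver (7.69%) and muscle lists (14.3%), at the lower edges of their ranges, and for the macrophage list (14.3%), whose range starts at 0%. Reads shared between gene copies were weighed too, but not for the olfactory receptors. That list was left out of this test, so shared reads stay open there. The macrophage (adjusted p = 0.0153), liver (adjusted p = 0.00600) and pluripotency lists (adjusted p = 0.00600) were still called by Fisher's exact test without their single multi-copy gene. Removing a single gene could change little, so this shows only that these calls do not rest on it. For the erythroid list, reads shared between copies stay open. Without its 4 globin genes 30% of 10 genes were marked (adjusted p = 0.234, Fisher's exact test). The smaller list could by itself lose the call.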

How the results depend on the processing

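The joining of peaks at most 500 bp apart was chosen only after the data were seen; the other alternatives were planned. No call reversed direction. Of the main results, 47 values stayed within their counting error (shared parts), within 1 SD between the 2 replicates (locations, 1.22 to 2.95 points) or within 1.5 times the main value (counts), and 40 moved by more. Of single lists and motifs, 279 values stayed on the same side of their threshold, 21 lost their call and 3 gained one. Among the 279, percentiles of cover that met no threshold crossed 50: nephron progenitors (18.27) at 79.93 with a 20 kb window and 83.68 with -log10 q of at least 5, proximal tubule (67.88) at 15.19 with 20 kb, cell cycle (62.79) at 43.42 with 100 kb, and loop and distal tubule (37.71) at 56.69 with -log10 q of at least 5 and 52.98 in the replicate 1 list. The HOX motif ratio (0.997) crossed 1, at 1.03 with -log10 q of at least 5 and 1.01 in the replicate 1 list. No paired analysis was possible because the series holds 1 group. Leaving out a replicate gives no overlap, correlation or count of unshared peaks, which need both. Depth is unknown and may set how many weak peaks each list holds; with only peaks of -log10 q of at least 5 kept in both lists, 2474 peaks in place of 23074 were unshared in replicate 1 and 24636 in place of 56862 in replicate 2. The cause of the other changes was not tested.

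The shared part of replicate 1 (75.3%) and of replicate 2 (50.5%) became 80.1% and 54.4% with an overlap of 1 bp, 42.0% and 34.1% with 50% of both peaks, 92.4% and 52.0% with -log10 q of at least 5 in both lists, 71.3% and 58.1% with equal numbers of top peaks, and 73.1% and 55.9% after joining peaks. Spearman's rho (0.620) and Pearson's r (0.715) became 0.611 and 0.710 with 1 bp, 0.803 and 0.879 with 50% of both peaks, 0.706 and 0.777 with -log10 q of at least 5, and 0.641 and 0.719 with -log10 p. Unshared peaks rose to 54254 in replicate 1 with 50% of both peaks and fell to 31589 in replicate 2 after joining.

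The promoter, gene body and intergenic shares (24.8, 44.4 and 30.8%) became 31.3, 39.6 and 29.1% with -log10 q of at least 5, 19.8, 47.9 and 32.3% in the pooled list and 31.6, 40.3 and 28.1% with all annotated transcripts. A 2 kb window gave promoters 28.3% and gene bodies 41.8%. Leaving out each replicate gave ranges of 18.5 to 22.7%, 46.5 to 48.9% and 30.8 to 32.6%. Lists at or above the 95th percentile of cover numbered 8, but 3 with a 100 kb window and 5 to 7 without 1 replicate. Of the top 20 domains, 12 were found again by covered bp and 15 to 18 without 1 replicate. The report names the lists whose promoter or cover calls were lost.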

Other observations

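All tests of gene families, chromosomes and CpG-matched lists in this part were chosen only after the data were seen. Families of at least 20 protein-coding genes sharing a symbol prefix were tested as the gene lists were. Fisher's exact test with Benjamini-Hochberg adjustment over 101 families called 48 marked more often and 29 less often than other genes. No family was matched on CpG content, along which marked shares ranged from 5.88% in the lowest decile to 91.3% in the highest. Members that lie side by side are not independent. The calls therefore do not tell family from CpG content or position. The mitochondrial ribosomal protein genes of the large subunit (Mrpl) were all marked, 49 of 49 in the replicated list and in both replicates (exact adjusted p = 2.14e-12), and 27 of 29 genes of the small subunit (Mrps) were (adjusted p = 2.07e-05). Vacuolar sorting genes (Vps) were marked in 34 of 35 (exact adjusted p = 9.96e-08), genes of cyclin-dependent kinases and associated proteins (Cdk) in 25 of 26 (adjusted p = 1.14e-05), and genes with the prefix of BTB zinc fingers (Zbtb) in 39 of 41 (adjusted p = 6.82e-08). Zinc finger genes (Zfp) were marked in 296 of 394, or 75.1% (exact adjusted p = 2.67e-16), while their marked members had little cover around them, 3403.5 bp, at the 0 percentile of 10000 random lists. Histone genes (Hist) showed the opposite surroundings: 58 of 67 were marked (exact adjusted p = 1.20e-07), with a median of 17811 bp within 50 kb (percentile 100), in clusters where neighbours share cover.

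Among the 29 families marked less often, vomeronasal receptors (Vmn) were marked in 1 of 331 (exact adjusted p = 1.20e-109), and taste receptors (Tas, 38 genes), keratin-associated proteins (Krtap, 57), kallikreins (Klk, 26), prolactins (Prl, 25), major urinary proteins (Mup, 22), protocadherin beta genes (Pcdhb, 22) and the reproductive homeobox genes (Rhox, 34) in 0 of the replicated list, with adjusted p from 2.18e-18 for Krtap to 1.65e-07 for Mup and Pcdhb. Cytochrome P450 genes (Cyp) were marked in 17 of 100 (exact adjusted p = 5.90e-13), and the marked ones had 1987 bp of cover (percentile 0.12). Among fibroblast growth factor genes (Fgf), 6 of 22 were marked (exact adjusted p = 0.0242). Many of these families are arrays of similar copies, in which reads that map to several copies can be lost. Of 948 coding genes on chromosome X, 36.2% were marked (35.2% in replicate 1 and 38.4% in replicate 2), against 44.0 to 62.1% on the autosomes; this difference was not tested.

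Against lists matched on promoter CpG content, 2 lists that did not pass the test against all genes lay outside their ranges. These ranges were not adjusted for the number of lists. Proximal tubule genes were marked in 68.8%, above the central 95% of matched lists (18.8 to 62.5%), with a median CpG observed to expected ratio of 0.271. CpG content was measured at the most 5' TSS, but marking counted any TSS. With 1 TSS per gene 50% of these genes were marked, inside that range. The range was not recomputed for that setting, so the match decides nothing here. Hox groups 12 and 13 were marked in 16.7%, below their matched range of 50 to 100%, with a ratio of 0.797. Hox genes of a cluster are not independent. Podocyte genes (71.4%, matched 50 to 85.7%), loop and distal tubule genes (42.9%, matched 21.4 to 64.3%) and adrenal cortex genes (14.3%, matched 0 to 57.1%) lay within theirs.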
